A study of Mus musculus and Acomys cahirinus with 10 samples.

How the data were processed

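The series held 10 single-cell RNA libraries of ear tissue, 5 from the house mouse Mus musculus and 5 from the spiny mouse Acomys cahirinus, made as 10x Chromium 3' version 2 libraries from cell suspensions. The spiny mouse is a rodent that closes ear punch wounds by regrowing tissue, whereas the house mouse scars, and the series design names injured ears of both species. The library titles joined the species with a number, 00, 03, 05, 10 or 15, and are used here as names (Mus03, Acomys03). The labels did not define the number, so it is given as a number and not as a time. The labels named macrophages as the cell type and the age as adult. Libraries 00, 03 and 10 of both species carried the date 20181217, called the December date here, and libraries 05 and 15 the date 20181127, the November date.

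The deposited files held raw UMI counts per gene and barcode for all 737280 barcodes of the 10x list, with no cell filter and no normalization by the authors. The submitters' processing notes named Cell Ranger 2.2.0 and the mouse build mm10. The Mus matrices had 28692 genes with mouse identifiers. The Acomys matrices had 24509 genes, of which 16184 carried a mouse symbol and 8324 only an identifier of a separate Acomys gene set, so those counts were made against another gene list, whose build is not given in the sources used here. After 718 Mus symbols were updated, 16083 symbols were shared, and tests between the species used these alone. The Mus list held 13 mitochondrial genes and the Acomys list 0, so no mitochondrial filter was applied. The Acomys list used here held no gene named Cxcl2, Spp1, Lyz2, Actb, Gapdh, S100a9 or Krt14. Each species was counted against its own gene models, so the species difference of a gene includes how completely its transcript is annotated in each list. Positions of named genes are from GENCODE M21 on mm10.

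A barcode was called a cell when its UMIs reached the 99th percentile of the top 3000 barcodes divided by 10 and it had at least 200 genes. This gave minimums of 4695, 7137, 4488, 6025 and 3485 UMIs for Mus00, Mus03, Mus05, Mus10 and Mus15, and 2872, 4975, 3848, 4562 and 1276 UMIs for Acomys00, Acomys03, Acomys05, Acomys10 and Acomys15. Doublet scores came from Scrublet in scanpy 1.11.5. Its automatic threshold marked 49 of 35001 called cells, so the highest scores were removed at a fixed rate of 0.8% per 1000 cells, which took out 1174 cells and left 33827. Cells were clustered separately in each species (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, leidenalg 0.10.2). Clusters were named from markers of 18 cell types. The type with the highest mean log2 marker fold was taken when that fold was at least 1.5 and at least 3 of its markers were detected in 10% of the cells. It also had to lead when the cluster was compared with cells of other types only, and to have more markers than any other type among the cluster's top 10 genes. Clusters without such a type were compared with the pooled macrophage-like, endothelial-like and fibroblast-like cells and named keratinocyte-like by the same fold and detection limits, when no other type had more markers among the top 10 genes. All other clusters were left unnamed. Names end in "-like" because they rest on RNA markers alone. The macrophage-like class was 1 cluster of 504 cells in Mus and 1 cluster of 1470 cells in Acomys. Sub-clusters of that class used 1500 variable genes, 20 components and resolution 0.5.

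Counts were summed over the cells of a class in each library, where a library had at least 10 such cells. Acomys00 had no macrophage-like cell, so 9 libraries entered the macrophage tests. Sums were tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, terms for number and species), with DESeq2 1.42.0 beside it, at an adjusted p of 0.05. Contrasts between numbers were made within one date: 03 against 00, 10 against 00, and 15 against 05. In the 03 against 00 and 10 against 00 contrasts the 00 side is Mus00 alone, since Acomys00 is empty for this class, while the other side draws on both species through the shared number term. Their p-values therefore take the spread from the other numbers and hold no measure of the spread at 00. The contrast of 10 against 03 was therefore added after the data had been seen, as were all tests in keratinocyte-like cells, the relative test and the sub-clusters. The relative test (4 numbers, 8 libraries, 4270 genes with at least 10 CPM) compared the ratio of macrophage-like to all other called cells of the same library between the species, so that a fixed factor from a gene's annotation cancels. The 16 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01, and again with an estimated correlation) and fry. In fry the directional p asks whether a list's genes move on balance one way, the mixed p asks whether they change in either direction, and neither compares the list with other genes. The lists were pro-inflammatory cytokines and enzymes, chemokines, alternative activation, tissue-resident macrophage, monocyte-derived, lipid-associated and phagocytic, interferon response, NF-kB feedback and immediate early, antigen presentation, growth and angiogenic factors, matrix and proteolysis, glycolysis and hypoxia, iron and oxidative stress, cell cycle, dissociation stress, and housekeeping as a negative control. For single libraries, the median log2 change of a list was set against 10000 random lists matched on expression.

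Shares of cells were compared with exact two-sided permutation tests over libraries, with Benjamini-Hochberg adjustment over 6 classes. The share of macrophage-like cells with a UMI was compared for 5 genes in cells thinned to 2000 UMIs each, again with exact permutation tests. Cxcl2 was measured in Mus only. Intervals are exact 95% binomial (Clopper-Pearson) or Poisson intervals, and a count of 0 is given with the limit of 3 counts. Both cover counting error only. The labels did not name animals, so p-values measure the spread between single libraries, which may be technical. With 1 library per species and number, contrasts between single libraries have no replicate check and carry no p.

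The sample groups, tests, gene lists, marker genes, alternatives and the rules for naming genes were fixed before the data were examined. The steps that turn markers into cluster names and the fixed doublet rate were set with the data at hand. For the species difference, named genes are the 10 largest changes in each direction among genes past the threshold, changed the same way in every number pair, with a mean of at least 20 CPM in both species. Mitochondrial, ribosomal protein, haemoglobin and unnamed genes were left out. For contrasts between numbers the rule names up to 8 genes per direction, and for each list up to 4 members. Some list members that the rule would name are not reported here. A further 13 genes were always given, among them Ltf and Vegfc because published work on spiny mouse ear macrophages names them. For the added relative test the same rule was used, with 20 CPM in macrophage-like cells of both species. Alternatives were another tool, RLE factors, no low-count filter, a fixed minimum of 1000 UMIs, doublets kept, resolution 2, all called cells, sums thinned to one depth, subtraction of a 5% ambient share (profile from barcodes of 10 to 100 UMIs), no number term, one date only, and leaving out each library.

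The edgeR workflow was tested on simulated data with 200 changed genes. For the species difference it recovered 42.4% of changes of log2 1 and 100% of changes of log2 2. For 03 against 00 it recovered 10.9% of changes of log2 2 and 42.9% of changes of log2 3. For 10 against 03 it recovered 96.5% of changes of log2 2, and for 15 against 05 21.0%. These macrophage-like simulations changed 200 of 5960 genes, up or down at random, from a mean profile common to both species. In the real species test most genes passed, a setting that they do not cover. The relative test recovered 81.2% of changes of log2 2, with 1.09% false calls. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.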

Results

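Single-cell RNA libraries of ear tissue were compared between the house mouse (Mus) and the spiny mouse (Acomys), with 1 library of each species at each of the numbers 00, 03, 05, 10 and 15. The libraries held 130039670, 54108615, 47103675, 128756454 and 56212386 UMIs for Mus00, Mus03, Mus05, Mus10 and Mus15. They held 71042559, 76816976, 39704074, 91244073 and 26934896 UMIs for Acomys00, Acomys03, Acomys05, Acomys10 and Acomys15. Cells kept numbered 6560, 1316, 2504, 4587 and 3300 in Mus and 4603, 2722, 1762, 3239 and 3234 in Acomys, in the same order.

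With the main processing keratinocytes, the cells of the epidermis, made up most of the kept cells in 8 of the 10 libraries. The labels gave macrophages as the cell type. With doublets kept they did not in Mus05 (1114 of 2556 cells), Mus10 (2287 of 4769) and Acomys05 (817 of 1788). With a fixed UMI minimum they did not in Acomys05 (992 of 4697) and Acomys10 (4026 of 8221). At the finer cluster resolution they did not in Acomys05 (588 of 1762) and Acomys10 (1311 of 3239). The keratinocyte-like share was 93.8% in Mus00 and 89.0% in Acomys00, and it was 14.5% in Mus03 and 38.4% in Acomys03. The share at 03 depended on the processing: it was 1.5% and 28.3% in Mus03 and Acomys03 with doublets kept, 29.1% and 21.9% with a fixed UMI minimum, and 33.2% and 18.6% at the finer cluster resolution. Macrophage-like cells, phagocytes marked by genes such as Csf1r and Mrc1, were 0.152% of Mus00 cells (95% interval 0.0731 to 0.280) and 0 of 4603 Acomys00 cells, which allows a share of up to 0.0652%. At 03 they were 20.1% of Mus cells (18 to 22.4) and 31.2% of Acomys cells (29.5 to 33). That order reversed at the finer cluster resolution, with 260 of 1316 Mus03 cells and 392 of 2722 Acomys03 cells. With a fixed UMI minimum both shares were lower, with 716 of 4948 Mus03 cells and 1300 of 7076 Acomys03 cells. Acomys00 then held 4 macrophage-like cells of 6461. At 05 the shares were 5.23% in Mus (4.39 to 6.18) and 16.4% in Acomys (14.7 to 18.2), at 10 they were 1.81% (1.44 to 2.24) and 9.42% (8.43 to 10.5), and at 15 they were 0.455% (0.255 to 0.749) and 0.835% (0.551 to 1.21). Clusters with no name held 54.8% of Mus03 and 24.8% of Acomys03 cells.

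**Figure D1:**
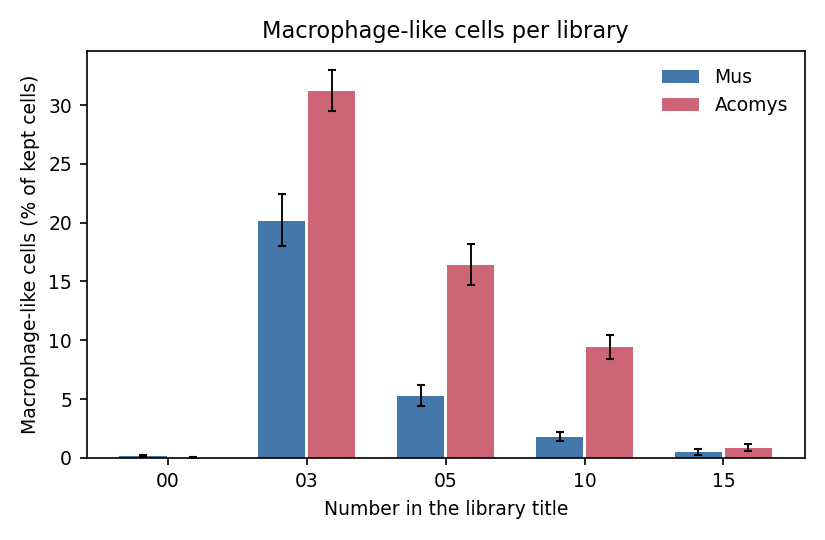
Macrophage-like cells as a percent of kept cells (y axis) by the number in the library title (x axis), Mus and Acomys side by side, with exact 95% binomial intervals as error bars. The share was highest at 03 in both species, at 20.1% in Mus and 31.2% in Acomys. At the finer cluster resolution, not drawn, the share at 03 was higher in Mus (260 of 1316 cells) than in Acomys (392 of 2722). With a fixed UMI minimum, also not drawn, it was lower than drawn in both species (716 of 4948 and 1300 of 7076 cells).

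The first comparison asked whether the cell classes took different shares in the 2 species. Macrophage-like cells were higher in Acomys in 4 of 5 number pairs, on average 11.6% ± 12.9 (SD, n = 5) against 5.56% ± 8.40 (n = 5) in Mus. The difference of 6.01 percentage points was smaller than the spread between libraries (exact permutation p = 0.421, adjusted 0.631, smallest p possible 0.00794). That spread includes the change of the share over the numbers. In the exact sign-flip test of the 5 number pairs p was 0.125 (adjusted 0.469, smallest p possible 0.0625). It was 6.17 points within the December date and 5.78 within the November date. Endothelial-like cells, which line vessels, had a mean share of 2.55% ± 2.07 in Acomys and 4.68% ± 2.62 in Mus (n = 5 each, exact p = 0.183, adjusted 0.548; −2.68 points within the December date and −1.30 within the November date). T cell-like cells had 0.671% ± 0.381 and 0.361% ± 0.233 (exact p = 0.151, adjusted 0.548; 0.206 and 0.467 points within the 2 dates). Keratinocyte-like (66.3% and 66.5%), fibroblast-like (1.29% and 1.90%) and pericyte or smooth muscle-like cells (0.252% and 0.233%) did not pass either, with adjusted p = 0.992, 0.631 and 0.992. Within dates the keratinocyte-like difference was 4.36 points on the December date and −7.03 on the November date, the pericyte one −0.143 and 0.263, and the fibroblast one −0.843 and −0.281. The macrophage difference was 1.11 points without Acomys03 and 9.66 without Mus03, 2.82 with a fixed UMI minimum and 0.649 at the finer cluster resolution. At that resolution it was −0.193 within the December date, and 3 of 5 pairs were higher in Acomys.

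The second comparison asked how many macrophage-like cells of each species held transcripts of activation genes, at equal depth. Mrc1, the mannose receptor of alternatively activated and resident macrophages (mouse chromosome 2, 14229392 to 14332057), was found in 52.2% ± 3.85 of Acomys cells (SD, n = 4) and 12.1% ± 7.99 of Mus cells (n = 5), higher in Acomys in 4 of 4 pairs. In the pairs of the December date the shares were 57.5% (54.1 to 60.8) against 23.4% (18.4 to 29.0) at 03 and 52.5% (46.7 to 58.2) against 3.61% (0.752 to 10.2) at 10. In those of the November date they were 48.8% (42.9 to 54.7) against 16.8% (10.8 to 24.3) at 05 and 50% (28.2 to 71.8) against 6.67% (0.169 to 31.9) at 15. In Mus00 it was 1 of 10 cells (0.253 to 44.5%). The Cd207-led, Langerhans-type sub-cluster was 70.0%, 1.51%, 3.05%, 21.7% and 60.0% of these cells in Mus00, 03, 05, 10 and 15, so the low Mus shares at 00 and 15 were not separated from that mix, while in Mus10 the 18 cells of it are too few to account for 3 of 83. The difference of 40.1 points had an exact permutation p = 0.00794, the smallest possible with 126 splits, and an adjusted p of 0.0397 over 5 genes. How completely Mrc1 is annotated in each gene list was not separated from this difference. Arg1, arginase, an enzyme of alternatively activated mouse macrophages (chromosome 10, 24915221 to 24927484), was found in 52.1% of Mus03 cells (45.9 to 58.2), 13.7% of Mus05 (8.35 to 20.8), 7.23% of Mus10 (2.70 to 15.1) and 13.3% of Mus15 (1.66 to 40.5). It was found in 0 of the macrophage-like cells of each Acomys library, which allows shares of cells with a UMI at this depth of up to 0.353%, 1.04%, 0.984% and 13.6% at 03, 05, 10 and 15, the last from the 22 of 27 cells that were deep enough. Cells without a UMI may still express the gene. Arg1 UMIs were counted in 0.146% of Acomys00 keratinocyte-like cells, so the gene was counted in the Acomys list. Over libraries the Arg1 difference (17.3% ± 20.2 in Mus, n = 5; 0% in Acomys, n = 4) did not pass (exact permutation p = 0.0873, adjusted 0.146), and it passed without Mus00, at −21.6 points (exact permutation, adjusted p = 0.0476).

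Il1b, the inflammatory cytokine interleukin 1 beta, was found in 38.0% ± 18.6 of Acomys and 32.9% ± 27.2 of Mus macrophage-like cells, with an exact permutation p of 0.754. The share was 69.8% in Mus03 (63.9 to 75.3) and 46.2% in Acomys03 (42.8 to 49.6), and 42.7% in Mus05 (34.1 to 51.7) and 59.9% in Acomys05 (54.0 to 65.6). At 10 it was 38.6% in Mus (28.1 to 49.9) and 18.7% in Acomys (14.5 to 23.5), and at 15 it was 13.3% (1.66 to 40.5) and 27.3% (10.7 to 50.2). Tnf, tumour necrosis factor, was found in 0.0865% ± 0.173 of Acomys cells and 2.89% ± 2.56 of Mus cells (exact permutation, adjusted p = 0.146). Without thinning, Tnf was found in 0.318% and 8.81% of cells and passed (exact permutation, adjusted p = 0.0397), as it did in thinned cells without Mus00 (difference −3.53 points, adjusted 0.0476). Nos2, inducible nitric oxide synthase, was found in 0% and 0.618% (adjusted p = 0.556, exact permutation). Leaving out Mus03, Mus05, Mus10 or Mus15 took the Mrc1 test to an adjusted p of 0.143 and leaving out any Acomys library to 0.0893, each with the smallest exact p that the remaining libraries allow. Keratinocyte-like cells served as the background. Mrc1 was in at most 2.29% of them (Acomys03), and Arg1 in 6.81% of those of Mus03. Il1b was in 45.5% of keratinocyte-like cells of Mus03, 21% of Acomys03 and 23.9% of Acomys05, so part of the Il1b detection in those libraries was shared with cells that are not macrophages. Median depths were 8763 and 7954 UMIs in macrophage-like and 33226 and 19755 UMIs in keratinocyte-like cells of Mus03 and Acomys03. Cxcl2, a neutrophil-attracting chemokine measured in Mus only, was in 82.6% of Mus03 macrophage-like (77.5 to 87.0) and 71.7% of keratinocyte-like cells (64.8 to 78.0).

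**Figure D2:**
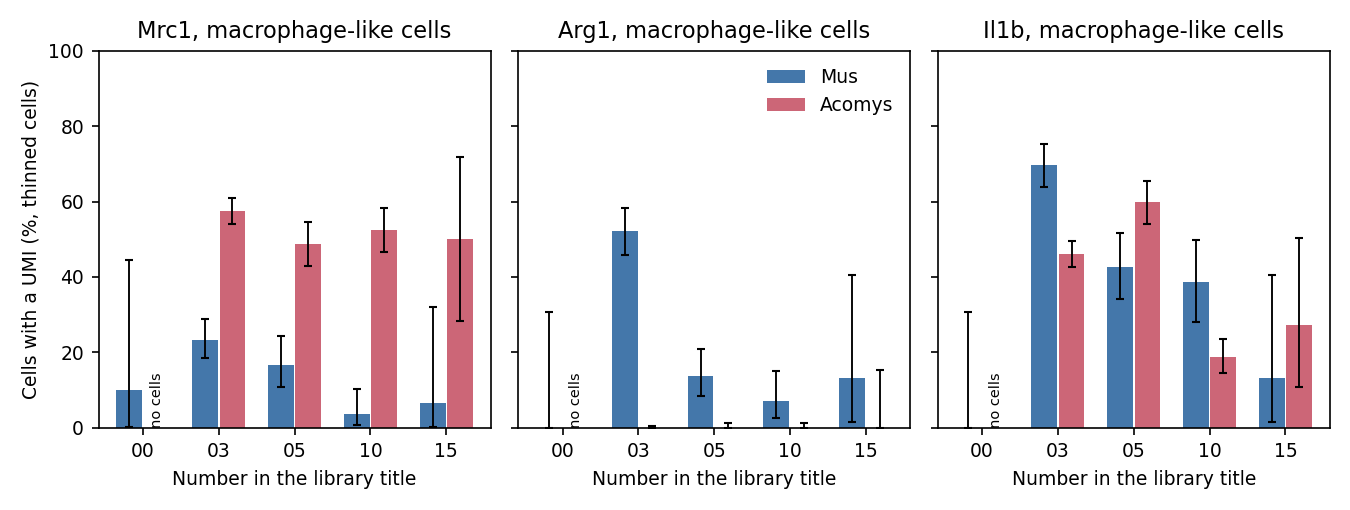
Percent of macrophage-like cells with at least 1 UMI of Mrc1, Arg1 or Il1b after thinning to 2000 UMIs per cell (y axis), by title number (x axis) in Mus and Acomys, with exact 95% binomial intervals. Mrc1 was at 48.8% to 57.5% in Acomys and 3.61% to 23.4% in Mus, and Arg1 was at 0% in each Acomys library with macrophage-like cells.

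The species difference in all genes of macrophage-like cells was large, and much of it was shared with keratinocyte-like cells. Of 5960 genes tested with edgeR, 3727 passed, 1664 higher and 2063 lower in Acomys. Higher genes in all 4 number pairs included the monocyte-attracting chemokines Ccl8 (log2 7.74 ± 0.50, SE) and Ccl12 (4.25 ± 0.77), the membrane protein gene Ms4a4a (7.27 ± 0.45), the chitinase-like Chil1 (5.76 ± 0.65), the sialic acid lyase gene Npl (5.26 ± 0.44) and the calprotectin subunit gene S100a8 (4.93 ± 0.60). S100a8 is also a gene of neutrophils and had 2143 CPM in Acomys03 endothelial-like against 13260 CPM in macrophage-like cells, so free RNA was not separated from part of it. Aga (4.65), Spc24 (4.18), Smagp (4.14) and Nme2 (4.11) completed the 10 largest. Lower genes included the actin regulators Arpc5 (−4.58 ± 0.25) and Capg (−4.30 ± 0.37), Gabarap of autophagy (−4.36), Cox7a2l (−4.21), Selenow (−3.96), Camk1 (−3.94), Fkbp1a (−3.90), Cops9 (−3.78), Tmed2 (−3.64) and Sdcbp (−3.63). The edgeR adjusted p of these 20 genes was at most 0.000382. In keratinocyte-like cells 8382 of 11063 genes passed, and Nme2 (5.09), Aga (4.07), Selenow (−4.72), Capg (−4.68) and Cops9 (−3.73) were also among the genes named there. Of 5850 genes tested in both classes, 1384 were higher in both and 1640 lower in both, where 686 and 708 were expected from the counts, and 133 moved in opposite directions. The correlation of the log2 differences across genes was 0.859 (Pearson; genes are not independent replicates). Fewer macrophage genes passed in sums thinned to one depth (331 of 804 tested) and with the November pairs alone (1613), and 4925 passed with the December pairs alone.

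**Figure D3:**
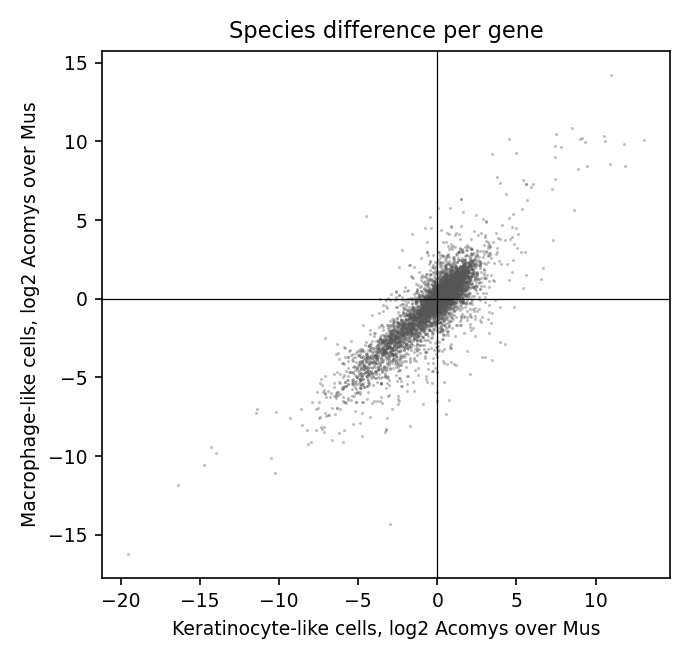
Species difference per gene as log2 Acomys over Mus in keratinocyte-like cells (x axis) and macrophage-like cells (y axis), 1 point per gene tested in both classes. The 5850 points lie along the diagonal, with a correlation of 0.859 across genes.

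Among the genes fixed in advance, Mrc1 was higher in Acomys (log2 2.66 ± 0.29, edgeR adjusted p = 6.89e-06), with 706, 464, 540 and 527 CPM in Acomys03, 05, 10 and 15 and 26.3, 182, 133, 51.2 and 44.5 CPM in Mus00, 03, 05, 10 and 15. The haemoglobin scavenger receptor gene Cd163 (3.00 ± 0.64, adjusted p = 0.00157) and the growth factor receptor gene Csf1r (1.08 ± 0.28, adjusted p = 0.00498) were also higher. Tnf (−4.27 ± 0.59, adjusted p = 4.63e-05) and Adgre1, which encodes the F4/80 antigen (−2.57 ± 0.41, adjusted p = 0.000137), were lower. Il1b did not pass (0.16 ± 0.52, adjusted p = 0.807). Of the genes in this paragraph only Il1b entered the relative test described below. For the others, Mrc1 among them, a difference in annotation was not set aside. Arg1 passed with 2535, 400, 117 and 356 CPM in Mus03, 05, 10 and 15 against 0 in the 4 Acomys libraries, whose limits were 0.414, 1.87, 1.27 and 35.9 CPM; in Mus00 it was also at 0, with a limit of 39.4 CPM. Vegfc, a lymphatic growth factor gene, had 38.1, 42.5 and 27.1 CPM in Acomys03, 05 and 10 and 1.59 (0.433 to 4.07), 1.10 (0.0279 to 6.13) and 0 CPM (limit 3.94) in Mus03, 05 and 10; in Mus00 and Mus15 it was at 0 with limits of 39.4 and 44.5 CPM, which do not exclude the Acomys level. Vegfa had 3.73, 10.6 and 1.69 CPM in Acomys03, 05 and 10 and 68.3, 25.3 and 14.4 CPM in Mus03, 05 and 10. Ltf, the lactoferrin gene, had 28.4, 24.3 and 9.72 CPM in Acomys03, 05 and 10, and in Mus03, 05 and 10 it had 0 (limit 1.19), 2.2 (0.266 to 7.95) and 0 CPM (limit 3.94), with the same wide limits at 0 UMIs in Mus00 and Mus15. Ltf was a leading gene of an Acomys sub-cluster with the neutrophil-type genes G0s2 and Pglyrp1 (1.77%, 2.77% and 0.656% of cells in Acomys03, 05 and 10, the last being 2 cells, 0.0795 to 2.35%), so its expression in macrophages is not shown. Nos2 reached 11.5 CPM in Mus03 and was at 0 in Acomys03 (limit 0.414). Spp1, osteopontin, was measured in Mus only, at 13.1, 1894, 731, 1127 and 549 CPM.

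Most gene lists split in both directions between the species. Of 12 pro-inflammatory genes tested, 1 was higher (Cd40, log2 0.98) and 5 lower in Acomys, among them Osm (−5.08), Cd86 (−2.88) and Clec4e (−2.84). Of 11 chemokines, 5 were higher, among them Ccl2 (3.77) and Ccl7 (3.20), and 2 lower, among them Ccl17 (−7.24). Of 10 antigen presentation genes, 2 were higher and 6 lower, among them H2-Ab1 (−8.72), Cd83 (−6.71) and Ciita (−5.37). Mus macrophage-like cells included a sub-cluster led by Cd207 (70.0% of Mus00, 21.7% of Mus10 and 60.0% of Mus15). Another was led by the dendritic cell marker Cd209a (24.4% of Mus05, 16.9% of Mus10). No Acomys sub-cluster was led by either gene, but both genes were counted in Acomys macrophage-like cells. Cd207 had 79.1 CPM in Acomys03 and 26.3 in Acomys10, against 57.8 in Mus03 and 198.8 in Mus10. Cd209a had 23.5 and 184.7 CPM in those Acomys libraries, against 67.9 and 34.75 in those Mus libraries. The Acomys sub-cluster led by Ccr2 (28.2% of Acomys10) also had Cd74, H2-Eb1 and H2-DMa among its leading genes. The antigen presentation list may therefore also follow the mix of cells, in either species. Of 17 lipid-associated and phagocytic genes, 8 were higher, among them Gpnmb (5.51), Ctsl (2.83) and Apoe (1.55), and 5 lower. Of 21 iron and oxidative stress genes, 9 were higher, among them Sod2 (2.94) and the haem-degrading Hmox1 (2.54), and 6 lower. Alternative activation had 3 higher (Fcrls, 4.51, beside Mrc1 and Cd163) and 3 lower (among them F13a1, −4.88) of 8, tissue-resident macrophage 3 and 5 of 12 (C1qc 1.91; Timd4 −6.58), and monocyte-derived 2 and 5 of 10 (Plac8 −6.67, Ccr2 −3.11). Interferon response had 1 and 4 of 7, NF-kB feedback 3 and 5 of 14 (Nfkb2 1.21, Socs3 −5.05), growth factors 1 and 2 of 8 (Vegfb 2.80), matrix and proteolysis 5 and 4 of 18 (Mmp9 3.11, Timp1 −1.61), and glycolysis 3 and 5 of 17 (Slc2a1 −3.40). Cell cycle had 1 and 0 of 15, dissociation stress 1 and 4 of 12, and the housekeeping control 4 and 2 of 9 (Gusb 1.12, Ywhaz −1.78). Adjusted over the list alone, the counts were the same except for monocyte-derived (2 and 6) and NF-kB feedback (2 and 5). No list passed camera (lowest adjusted p = 0.580; adjusted p = 0.929 with an estimated correlation) and none passed fry (lowest adjusted p = 0.0695). For alternative activation, matrix, glycolysis and cell cycle the median change was negative (−0.01, −0.57, −0.15 and −0.10) while camera ranked the list upward. For lipid-associated genes the median was 0.80 and the mean −0.15.

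To set aside factors that act on a gene in every cell, macrophage-like cells were compared with the other cells of the same libraries. Relative to those cells, 879 of 4270 genes passed with edgeR, 456 relatively higher and 423 relatively lower in Acomys macrophage-like cells. Npl had the largest shift (log2 7.41 ± 0.30, adjusted p = 1.28e-08; mouse chromosome 1, 153503015 to 153550045). It had 907 CPM in macrophage-like and 15.2 CPM in other cells of Acomys, and 49.5 and 98.4 CPM in those of Mus. Chil1 (4.47 ± 0.43), Ccl8 (4.05 ± 0.65), the acid nuclease gene Dnase2a (3.96), B4galnt1 (3.79), Rgcc (3.76), Smagp (3.67), S100a8 (3.54), the xanthine dehydrogenase gene Xdh (3.34) and Tent5a (3.22) were also relatively higher. The prostaglandin-degrading enzyme gene Hpgd (−4.88 ± 0.78), the cytokine gene Il18 (−4.11 ± 0.28), Epcam (−3.77 ± 0.76), Ntpcr (−3.67), Camk1 (−3.51), Slfn2 (−3.02), Ccl6 (−2.76), the leukotriene synthesis gene Alox5ap (−2.75), Ifitm3 (−2.70) and Ncoa7 (−2.70) were relatively lower. All of these relatively lower genes but Camk1 and Slfn2 had more CPM in the other cells of Acomys than of Mus. Ncoa7 had 37.1 CPM in Mus and 47.3 CPM in Acomys macrophage-like cells, and 11.1 and 130 CPM in the other cells. Il18 had 81.0 and 43.3 CPM in macrophage-like cells and 14.0 and 146 CPM in the others. A relative fall is therefore not by itself a lower level in macrophage-like cells. Epcam was a leading gene of the Cd207-led sub-cluster, which was 60.0% of Mus15 macrophage-like cells, so its value was not separated from that mix.

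In the relative test, lipid-associated and phagocytic genes had 5 of 11 members higher (Gpnmb 3.93, Ctsd 2.75, Apoe 1.46, Cd63 0.96 among them) and 1 lower (Lipa −1.96); adjusted over the list alone, 6 and 1. Antigen presentation had 3 of 7 lower (Cd74 −2.52, H2-Eb1 −2.43, H2-DMa −1.68). Iron and oxidative stress had 7 of 15 higher (Mt2 2.37, Hmox1 1.53, Sod2 1.31 among them) and 4 lower (Hp −4.47 among them), and NF-kB feedback 3 of 12 higher (Icam1 1.67, Nfkb1 1.39, Nfkb2 0.65). Of the other lists, matrix had 2 of 14 higher and 3 lower (Timp2 1.89, Timp1 −2.77), glycolysis 1 of 15 higher and 2 lower, pro-inflammatory genes 1 of 4 higher (Ptges 2.72) and 1 lower (Il18), chemokines 1 of 9 higher and 1 lower, monocyte-derived 2 of 6 lower (Cd9 −1.98 beside Hp), growth factors 1 of 6 lower (Areg −3.04), cell cycle 2 of 15 lower, dissociation stress 1 of 11 lower and alternative activation 0 of 3. Adjusted over the list alone, matrix had 2 and 4, iron 7 and 5, growth factors 0 and 2 and cell cycle 0 and 1, and the remaining lists kept their counts. No list passed camera (lowest adjusted p = 0.112, for the lipid list; adjusted p = 0.613 with an estimated correlation). By fry, pro-inflammatory (adjusted p = 0.00586, median −0.67) and monocyte-derived genes (0.0223, median −0.41) passed. The housekeeping control passed too (0.0260, median 0.19, with 2 of 9 higher and 1 lower; adjusted over the list alone, 3 and 1), so fry did not separate these lists from genes chosen as unchanging. Il1b, the only always-given gene that entered this test, did not pass (−1.11, edgeR adjusted p = 0.358). Leaving out the 05, 03 or 10 pair gave 451, 495 and 534 genes.

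**Figure D4:**
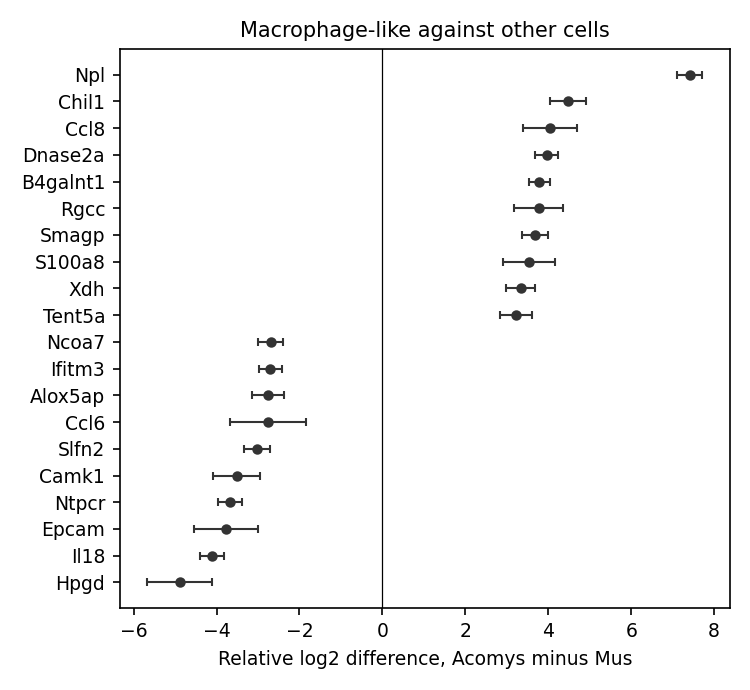
Relative log2 difference, Acomys minus Mus, of macrophage-like against other cells of the same libraries (x axis) for the 20 named genes (y axis), with standard errors. Npl lies highest at 7.41 and Hpgd lowest at −4.88.

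The change from 00 to 03 in macrophage-like cells was tested against the 10 cells of Mus00 alone, since Acomys00 had no such cell, so the p-values rest on the spread at other numbers. The 03 side pooled Mus03 and Acomys03. Of 5960 genes, 25 passed with edgeR (12 higher, 13 lower; 672 at an unadjusted p under 0.05; 51 with DESeq2). Arg1 was at least 64.4-fold higher in Mus03 than the limit of its 0 UMIs in Mus00 (2535 CPM over 39.4), the endotoxin co-receptor gene Cd14 at least 42.1-fold, the monocyte chemokine gene Ccl2 at least 32.8-fold, the complement receptor gene C5ar1 at least 9.94-fold and the protease inhibitor gene Timp2 at least 4.14-fold. Clec4d (log2 6.14 ± 1.11), Srgn (5.46 ± 0.85) and the hypoxia factor gene Hif1a (4.83 ± 0.81) also rose, from 1, 4 and 1 UMIs in Mus00. The single UMI of Clec4d and of Hif1a (13.1 CPM) lies below the limit of 39.4 CPM, so these 2 folds are not well measured. In Mus03 they had 1109 and 385 CPM. Genes that fell included the keratin gene Krt10 (−4.82 ± 0.81), the lipid receptor genes Ffar2 (−4.52) and Lpar3 (−4.36), the eicosanoid enzyme genes Alox5 (−4.07) and Ptgs1 (−3.97), Dapl1 (−3.79), Ly6g6c (−3.60) and Fam25c (−3.58). Krt10, Dapl1, Ly6g6c and Fam25c are genes of keratinocytes, which were 93.8% of Mus00 cells, so their fall is not shown to be a change within macrophages. In Mus00, 7 of the 10 cells (70.0%, 34.8 to 93.3) belonged to a sub-cluster led by Cd207 and Epcam, genes of Langerhans cells, whose leading genes also included Ptgs1 and Lpar3. That sub-cluster held 4 of 265 cells in Mus03. The edgeR count was 158 without Acomys03, 132 without Acomys05, 95 without Mus10, 83 without Mus05, 66 without Acomys10, 66 without Acomys15 and 34 without Mus03, and it was 4 after subtraction of ambient RNA. Without Mus00 the contrast could not be fitted.

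By camera, 8 lists were higher at 03 than 00. Chemokines had adjusted p = 0.00166, glycolysis 0.00574, matrix 0.00711, alternative activation and NF-kB feedback 0.0249, pro-inflammatory and iron genes 0.0326, and lipid-associated genes 0.0441. With an estimated correlation none held (adjusted p = 0.608 for each of the 8). Over all genes 1, 1, 2, 1, 0, 0, 0 and 0 members rose in chemokines, glycolysis, matrix, alternative activation, NF-kB feedback, pro-inflammatory, iron and lipid-associated lists. Adjusted over the list alone, 4 of 11, 9 of 17, 10 of 18, 5 of 8, 5 of 14, 4 of 12, 6 of 21 and 7 of 17 rose, and 1 pro-inflammatory gene fell.

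For 10 against 00, again with Mus00 as the only 00 library, 0 genes passed with edgeR (436 at an unadjusted p under 0.05; 10 with DESeq2). Chemokines alone passed camera (adjusted p = 0.0164; adjusted p = 0.817 with an estimated correlation), with 0 of 11 members past the threshold over all genes and 0 adjusted over the list alone. The edgeR count was 45 without Mus03, 17 without Acomys03, 16 without Acomys05, 5 without Mus05 and 1 without Acomys10.

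For 15 against 05, in both species, 0 genes passed with edgeR (568 at an unadjusted p under 0.05; 9 with DESeq2). No list passed camera, with a lowest adjusted p of 0.0891 for the interferon and monocyte-derived lists. With an estimated correlation the lowest adjusted p was 0.910. Over all genes 0 members passed. Adjusted over the list alone, 5 of 10 monocyte-derived, 3 of 18 matrix, 3 of 21 iron, 2 of 12 pro-inflammatory, 1 of 8 growth factor and 1 of 7 interferon genes fell, and of 12 tissue-resident genes 1 rose and 1 fell. The libraries at 15 held 15 and 27 macrophage-like cells, and sub-cluster shares differed from 05: the Cd207-led one held 60.0% in Mus15 and 3.05% in Mus05, the Acp5-led one 0 of 15 cells (limit 20%) and 46.6%, the Acomys one led by Ccl3 and Il1b 25.9% and 57.4%, and the Acomys one led by Mmp9 48.1% and 28.0%. These falls were not separated from that mix. The count was 44 without Mus03, 38 without Acomys03, 20 without Acomys05, 14 without Mus05, 12 without Mus10, 10 without Acomys10, 4 without Acomys15 and 3 without Mus00.

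The added contrast of 10 against 03 had macrophage-like cells of both species on one date (83 and 305 at 10, 265 and 849 at 03). Macrophage-like cells of both species had lower medians of monocyte and inflammatory genes at 10 than at 03. Arg1 (log2 −4.51 ± 0.49, edgeR adjusted p = 0.0117) and the monocyte gene Plac8 (−3.40 ± 0.35, adjusted p = 0.00269) fell and Lpar3 rose (4.14 ± 0.53, adjusted p = 0.0117). These 3 genes, named after their values were seen, were the only ones of 5960 to pass (500 at an unadjusted p under 0.05; 3 with DESeq2), and Arg1 was at 0 in both Acomys libraries. Lpar3 was a leading gene of the Cd207-led sub-cluster, which went from 1.51% of Mus03 to 21.7% of Mus10 cells. The Areg-led one went from 35.5% to 3.61% (0.752 to 10.2), the interferon-led one from 12.8% to 0 of 83 cells (limit 3.61%), the Acomys one led by Gas6 from 0.589% to 33.1% and the Acomys one led by Ccr2 from 20% to 28.2%, so the changes in this contrast were not separated from the mix of sub-clusters. By camera, 9 lists were lower at 10: glycolysis (adjusted p = 1.08e-07), monocyte-derived (1.36e-07), NF-kB feedback (1.75e-05), alternative activation (3.23e-05), chemokines (0.000833), interferon response (0.0011), matrix (0.00136), growth factors (0.00167) and pro-inflammatory genes (0.00862). Cell cycle genes were higher (7.34e-07). None held with an estimated correlation (adjusted p = 0.230 to 0.389) or by fry (lowest adjusted p = 0.334). Over all genes, 1 of 10 monocyte-derived genes (Plac8) and 1 of 8 alternative activation genes (Arg1) fell. Adjusted over the list alone, 6 of 10 monocyte-derived, 5 of 7 interferon, 5 of 17 glycolysis, 5 of 18 matrix, 3 of 11 chemokine, 3 of 8 alternative activation, 3 of 8 growth factor and 1 of 14 NF-kB genes fell, 2 of 15 cell cycle and 1 of 18 matrix genes rose, and 0 of 12 pro-inflammatory genes passed. Tissue-resident genes did not pass camera and had 0 of 12 past the threshold over all genes, and 4 higher and 2 lower adjusted over the list alone. In single libraries the median change of the monocyte-derived list was −2.40 in Mus and −1.09 in Acomys, and of the interferon list −2.15 and −0.95. With members at 0 set to their limit, the glycolysis median was −1.05 in Mus and −0.14 in Acomys. On that measure NF-kB feedback had −0.77 and −0.38 and alternative activation −0.90 and −0.32. Of the 9 lists only growth factors fell more in Acomys (−0.07 and −0.62), so the pooled calls rest more on Mus. The cell cycle median was 1.56 in Mus, where 9 cells of Mus10 formed the mitotic sub-cluster, and 0.22 in Acomys, at percentile 92.6 of random lists. The tissue-resident medians were −0.03 and 1.24; with members at 0 set to their limit the last pair was 0.12 and 1.26. The gene count was 137 without Acomys03, 85 without Acomys05, 35 without Mus05, 23 without Acomys10, 11 without Mus03, 6 without Acomys15, 2 without Mus00 and 1 without Mus10 or without Mus15, and it was 0 in sums thinned to one depth.

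Macrophage-like sub-clusters differed between libraries. In Mus03, 37.7% of 265 cells (31.9 to 43.9) were in a sub-cluster led by Pf4, Folr2 and Ccl12, 35.5% (29.7 to 41.6) in one led by Areg, Ptgs2, Thbs1 and Vegfa, and 12.8% (9.05 to 17.5) in one led by the interferon-induced genes Rsad2, Cxcl10 and Ifit3. In Mus05, 46.6% of 131 cells (37.8 to 55.5) were led by Acp5 and Nfatc1, genes of osteoclast-type cells, and 24.4% (17.3 to 32.7) by the lectin genes Mgl2 and Cd209a. In Mus10, 10.8% of 83 cells (5.08 to 19.6) were led by the mitotic genes Cenpf and Ccnb2. In Acomys03, 25.1% of 849 cells (22.2 to 28.1) were led by Cxcl5 and Phlda1, 20% (17.4 to 22.9) by Ccr2, Ly86 and Cd74, and 15.7% (13.3 to 18.3) by Ccl8, Apoe and C1qa. In Acomys05, 57.4% of 289 cells (51.5 to 63.2) were led by Ccl3, Il1b, Ptges and Nlrp3 of the inflammasome and 28.0% (22.9 to 33.6) by Mmp9 and Cd36. These 2 sub-clusters held 25.9% and 48.1% of Acomys15, also of the November date, but 0.589% and 0.118% (1 cell, 0.00298 to 0.654) of Acomys03 and 0 of 305 cells of Acomys10 (limit 0.984%), so number and date were not separated. In Acomys10, 33.1% of 305 cells (27.9 to 38.7) were led by Gas6, Slc40a1, Selenop and Igf1, genes of resident and iron-recycling macrophages, and 28.2% (23.2 to 33.6) by Ccr2 and Ly86. The species were clustered separately and each number is 1 library, so these shares were not tested.

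The last comparison asked whether the change from 00 to 03 over all called cells ran in parallel in both species. Across 5604 genes the log2 changes had a Pearson correlation of 0.728 and a Spearman correlation of 0.607, and 75.5% of genes had the same sign. At least 2-fold changes were shared upward by 381 genes and downward by 165, and 27 genes moved at least 2-fold in opposite directions. From 00 to 03 the keratinocyte-like share fell and the macrophage-like share rose in both species. The agreement over all called cells was therefore not separated from a shared change of the cell mix. Within keratinocyte-like cells the Pearson correlation was 0.659 across 5329 genes. The largest differences, as values of single libraries, were a higher log2 change in Acomys for the protease gene Mmp3 (Acomys minus Mus, 7.93) and Npl (7.75), which were higher at 03 than 00 in Acomys and lower in Mus, and for H2-Eb1 (3.58) and Hmox1 (3.01), which were higher at 03 in both. Slurp1 (5.13), Mt4 (4.89), Lor (4.51) and Crct1 (3.65), genes of the outer epidermis, were lower at 03 in both species and by more in Mus. Within keratinocyte-like cells the differences were 7.53 for Slurp1, 3.63 for Mt4, 4.89 for Lor, 4.54 for Crct1 and 8.06 for Mmp3. There Slurp1 and Crct1 were slightly higher at 03 in Acomys (log2 change 0.36 and 0.35). The fall of the keratinocyte-like share alone therefore does not account for these 5. A changed mix within that class was not separated: Mus03 held 191 such cells, 20 with doublets kept and 437 at the finer cluster resolution. For the other genes named here the cell mix was not separated. The hair follicle keratin genes Krt71 (−12.17) and Krt25 (−9.94), together with G0s2 (−5.44), Gpx2 (−4.90), Mpeg1 (−4.11), Elovl3 (−4.07), Mfge8 (−4.03) and Akr1c18 (−3.94), had the higher log2 change in Mus.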

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

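The tests of barcode sharing were chosen only after these results had been seen.

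Npl, Krt71, Krt25 and Akr1c18 moved in opposite directions from 00 to 03 in the 2 species. Over all called cells, Npl went from 298 to 74.3 CPM in Mus and from 3.46 to 242 CPM in Acomys, a difference of 7.75 in log2 change. Krt71, a keratin of the inner root sheath of the hair, went from 0.492 to 137 CPM in Mus and from 261 to 4.24 CPM in Acomys (difference −12.17). Krt25, of the same sheath, went from 0.474 to 86.4 CPM in Mus and from 367 to 21.2 CPM in Acomys (−9.94). Akr1c18, a steroid-reducing enzyme gene, went from 17.2 to 82.4 CPM in Mus and from 889 to 264 CPM in Acomys (−3.94). Each value is 1 library and the difference was not tested. Macrophage-like cells went from 0 (limit 0.0652%) to 31.2% of Acomys cells, and Npl had 907 CPM in macrophage-like and 15.2 in other cells of Acomys against 49.5 and 98.4 in Mus, so the moves of Npl were not separated from the cell mix. Krt71 and Krt25 were higher at 03 in Mus while the keratinocyte-like share fell from 93.8% to 14.5%, and within keratinocyte-like cells Krt71 differed by −8.15 at 10 against 00.

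A small cluster led by Scgb1a1, the secretoglobin of airway club cells, appeared at the lower limit of 1000 UMIs. It held 28 cells in Mus05 (0.655%, 0.436 to 0.945), 32 in Mus15 (0.693%, 0.475 to 0.977), 16 in Acomys05 (0.341%, 0.195 to 0.553) and 21 in Acomys15 (0.599%, 0.371 to 0.914), the 4 libraries of the November date. It held 0 cells in the 6 libraries of the December date, which allows at most 0.0606% in the library with the fewest cells of them. Scgb1a1 reached 50647 CPM in the Mus and 37017 CPM in the Acomys cluster, against 55.3 and 1.29 CPM in the next highest cluster. If each ear sample held such cells, their barcodes would differ between libraries, but 100% of them were found with at least 300 UMIs in the other November library of the same species. Of the Acomys barcodes 100% were also found in Mus05 and Mus15, where 1.20% and 1.27% were expected. Cells of another tissue in a pool sequenced with these libraries are a candidate source, which was not tested further.

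Barcodes were shared beyond chance between same-species libraries of one date. For same-species pairs of one date the observed number of shared barcodes was a median of 2.37 times the expected number (8 pairs, 1.33 to 8.86), which argues against chance sharing. For same-species pairs of different dates the median ratio was 0.934 (12 pairs, 0.691 to 1.16), as reads swapped between libraries run together would give, if the species were run apart in December, which the labels do not say. For pairs of different species on one date it was 1.08 (0.775 to 2.31). The 4 November pairs lay at 1.68 to 2.31 and the December pairs at 0.775 to 1.21, so sharing across species was limited to the November date, and why was not tested. No biological explanation was tested. Removing cells whose barcode had more UMIs in another library of that date gave 3689 species calls against 3727.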

How the results depend on the processing

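The contrast of 10 against 03, the relative test and the keratinocyte-like tests, and for the planned tests the alternatives without the Cd207-led sub-cluster, without shared barcodes and without Mus00 and the 15 pair, were chosen only after results had been seen. Of 24 alternatives of the species count in macrophage-like cells, 20 stayed within 1.5 times of 3727, and the keratinocyte-like species count did so in all 12 (7863 to 8299 when 1 library was left out). Without the number block the species count was 3488. With each gene's species mean removed and the number effect left in, same-number libraries of the species correlated little (0.0974, 0.0618, 0.114 and 0.0281). Mus03 with Acomys05, of another number, had 0.119. The changes between numbers were thus mostly not shared by the species. For each change below the cause was not tested. Depth limits most what can be said of Mus00, Mus15 and Acomys15, with 10, 15 and 27 macrophage-like cells. The leave-one-out run without Mus00 could not be fitted for 03 or 10 against 00.

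The species count was 6039 with no filter, 8932 over all called cells, 331 in thinned sums, 1613 with the November pairs, and 2652 to 4826 with 1 library left out. For 03 against 00 it was 51 with DESeq2, 230 with no filter, 1343 over all cells, 5 thinned, 4 after ambient subtraction, and 32 to 158 with 1 library left out. For 10 against 00 it was 10 with DESeq2, 72 with no filter, 282 over all cells, and 0 to 45 with 1 library left out. For 15 against 05 it was 9 with DESeq2, 6 with RLE, 149 with no filter, 1 with the fixed minimum, 3 with shared barcodes removed, and 0 to 44 with 1 library left out. For 10 against 03 it was 7 with RLE, 188 with no filter, 5 with the fixed minimum, after ambient subtraction, without the Cd207-led sub-cluster and without Mus00 and the 15 pair, 0 over all cells, at resolution 2 and thinned, and 1 to 137 with 1 library left out.

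In keratinocyte-like cells, 03 against 00 gave 1387 genes with DESeq2, 202 after ambient subtraction and 1 to 528 with 1 library left out. For 10 against 00 it gave 662, 17 and 0 to 101, and for 15 against 05 108 with DESeq2 and 0 to 3. The relative count was 451 to 939 with 1 pair left out. Of the 9 list calls in the number contrasts fixed beforehand, 0 held with an estimated correlation.

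The keratinocyte-like share difference was 10.3 with doublets kept, −19.5 with the fixed minimum, −17.8 at resolution 2 and −13.2 to 6.78 with 1 library left out, the pericyte one −0.142 to 0.0771, and the fibroblast one 0.247 with the fixed minimum and 1.10 at resolution 2 (adjusted p = 0.143, exact permutation). The mean macrophage, T cell and endothelial differences kept their sign and did not pass in any of 15 alternatives each. In thinned cells the Mrc1 difference was 38.0 to 42.9 with 1 library left out and 39.6 in the exact sign-flip test of the number pairs, where the smallest p possible is 0.125. Tnf was −8.49 without thinning and −3.53 to −1.86 with 1 library left out, Arg1 −21.6 to −8.58, and Il1b −3.11 in the sign-flip test and −3.11 to 14.3. The correlation of the 03 against 00 change between the species was 0.767 at 50 CPM against 0.728.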

Other observations

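The tests in keratinocyte-like cells, the relative test, the neutrophil-type clusters, the gene model and Cd207 tests and the tests on free RNA were chosen only after results had been seen. For the splits of the libraries, what each outcome would mean was written down before they were run.

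Keratinocyte-like cells changed between 00 and 03 in both species. Of 11063 genes 535 passed with edgeR, 290 higher and 245 lower. Genes that fell included Serpinb12 (log2 −5.30 ± 0.86), the keratin genes Krt78 (−4.68 ± 1.01), Krt23 (−4.47), Krt24 (−4.35) and Krt10 (−3.94), Serpinb13 (−4.34), Ly6g6c (−4.25) and the histidine-degrading Hal (−4.14). The heat shock gene Hspb1 also fell (−3.05). Of 17 cell cycle genes 4 rose, among them Ccnb1 (1.47), Ccna2 (1.44) and Birc5 (1.36), and 15 adjusted over the list alone (camera adjusted p = 8.12e-08; adjusted p = 0.149 with an estimated correlation). Of 18 glycolysis and hypoxia genes 8 rose, among them Slc16a3, taken up below, Pfkfb3 (3.57), the glucose transporter gene Slc2a1 (1.71) and Ldha (1.39), and 13 adjusted over the list alone (camera adjusted p = 9.99e-08; adjusted p = 0.139 with an estimated correlation). The count of genes was 1 without Acomys00, 20 without Mus03, 101 without Mus00 and 286 without Acomys10, and 202 after subtraction of ambient RNA. Across 5329 genes the change correlated between the species (Pearson 0.659). For 10 against 00, 7 genes passed, with the lactate transporter gene Slc16a3 (5.34), also part of the second pattern below, higher and Msx2 (−2.02), Cd82 (−2) and Hdac5 (−1.76) lower in both species. Without 1 library that count was 101 (Mus03), 44 (Acomys03), 12 (Acomys15), 2 (Mus00), 2 (Mus15), 1 (Mus05) and 0 (Mus10, Acomys00, Acomys05 or Acomys10). For 15 against 05, 0 genes passed with edgeR (540 at an unadjusted p under 0.05; 108 with DESeq2), and 3 without Acomys03.

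Neutrophil-type cells lay almost wholly below the UMI minimum of the cell calls. At 1000 UMIs, clusters with neutrophil markers held 44.6% of Mus03 cells (43.2 to 46.0) and 29.8% of Acomys03 cells (28.8 to 30.9). At 05 they held 7.88% in Mus (7.09 to 8.73) and 38.0% in Acomys (36.7 to 39.4), at 10 5.38% (4.92 to 5.87) and 11.1% (10.4 to 11.8). At 00 they held 0.0557% in Mus and 0 of 6461 cells in Acomys (limit 0.0464%), and at 15 0 of 4615 cells in Mus (limit 0.0650%) and 0.399% in Acomys. In Acomys03 99.9% of these cells, and in Mus03 100%, lay below the main minimum.

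The other splits of the libraries asked whether the species calls could arise by chance. In macrophage-like cells, 1 of 32 splits of the 8 paired libraries gave as many calls, the real one with 3867, and the highest other gave 0. In keratinocyte-like cells it was 1 of 100 splits (8382; highest other 0), and in the relative test 1 of 35 (879; highest other 326). The real split ranked first for each of these 3 counts. Every other split mixed the species, so the species effect widened the spread within groups, which lowers the calls. The splits therefore do not exclude chance. The real split also separates the gene lists that were used for counting, so these counts do not tell a species difference from a difference in annotation.

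The first pattern weighed is the species difference itself. Of the macrophage calls also tested in keratinocyte-like cells, 91.8% had the same sign there, as differing gene models could give; a species difference common to all cells would give that too, so the shared part cannot be told apart from annotation. A factor fixed per gene cancels in the relative test, where 879 genes passed, which argues against gene models as the whole source of the macrophage-specific part. For the Cd207-led, Langerhans-type cells among Mus macrophage-like cells the test cannot decide. In the 6 libraries of the 03, 05 and 10 pairs, 934 genes passed without these cells and 939 with them. That run left out only 4, 4 and 18 cells of Mus03, Mus05 and Mus10. It did not hold the 15 pair, where 9 of 15 Mus cells were of this kind. A similar count also does not show that the same genes passed. Epcam was at −3.77 in all 8 libraries and at −2.38 in the 6 without these cells. A species difference in macrophage-like cells or in the cells they were compared with remains open as a hypothesis.

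The second pattern is the rise at 03 in keratinocyte-like cells of genes that were higher in macrophage-like cells: Il1b (log2 8.42 ± 1.18), Ccl3 (8.38), Ccl4 (8.21), Srgn (7.61), Fcer1g (6.73), Tyrobp (6.29), Ncf4 (6.21) and Slc16a3 (6.01), each with an edgeR adjusted p of at most 0.0314. If keratinocyte-like cells transcribed these genes and endothelial-like and fibroblast-like cells did not, the latter would hold far less. Their CPM was a median of 1.06 times that of keratinocyte-like cells in Mus03 (0.684 to 1.60) and 1.29 times in Acomys03 (0.531 to 3.76) over these 8 genes, as free RNA from leukocytes would give, while in macrophage-like cells it was 6.39 and 19.5 times. Doublets are argued against by the share of thinned keratinocyte-like cells with an Il1b UMI, which was at least 21% in both 03 libraries. Transcription in all of these classes would also give similar levels, so the ratios do not exclude transcription in keratinocyte-like cells. With that spread free RNA is a candidate source for most of these genes and not shown for each. The neutrophil-type cells below the UMI minimum may have contributed, which was not tested.

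Across genes, the change from 03 to 10 in macrophage-like cells correlated little between the species (Pearson 0.275) and the change from 05 to 15 less (0.0462). In single libraries, Chil1 (log2 4.23), G0s2 (4.28), Thbs1 (3.99) and Ccl6 (3.87) had the higher change from 03 to 10 in Acomys and Cd207 (−3.32) in Mus.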
